A study of Homo sapiens with 4 samples.

How the data were processed

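The series holds 4 sequencing libraries of NCI-H1944, a human lung adenocarcinoma cell line described in the labels as wild type. Per the labels' protocols, cells received 100 nM of BAY-1217389, an inhibitor of the mitotic kinase MPS1 (gene TTK), or DMSO as the solvent control, for 48 h. The drug was then washed out and the cells were cultured for another 24 h. Per the labels' protocols, 10% of the lysate was kept as total RNA (Input), and the remainder was immunoprecipitated with J2, an antibody that binds double-stranded RNA (dsRNA). Per the labels' protocols, RNA was purified with TRIZOL and a miRNeasy column. Libraries were made with the SMARTer stranded total RNA kit and converted for DNBSEQ sequencing, per the labels' protocols. The groups were taken from the sample titles and are DMSO Input, MPS1i Input, DMSO J2 and MPS1i J2, with 1 library in each of the 4 groups.

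The deposited values are raw, whole-number read counts per stranded genomic region in 2 tables, 1 for the Input libraries and 1 for the J2 libraries. Trim Galore, Trimmomatic, cutadapt, STAR, featureCounts and HOMER are named, without versions or roles, per the submitters' processing notes. The genome build is GRCh38 (hg38), per the submitters' processing notes. Per the file headers, every region carries its position, strand and length, an annotation by HOMER (intron, intergenic, promoter-TSS and others) with a nearest gene, and the repeat lying on its strand. How the regions were called, how reads mapping to several places were counted, and whether duplicate reads were removed are not given in the sources used here. No spike-in was used here, so every value is relative to the reads of its own library.

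The 2 tables have separate sets of regions, 2310971 for Input with a median length of 128 bp and 3814162 for J2 with a median length of 120 bp. No read in either library was found for 47.4% of the regions for Input and 49.9% of those for J2. Only 0.205% and 0.157% of the regions of the Input and J2 tables overlapped an annotated exon on the same strand. Outside the mitochondrial genome, such regions held 3.42% of the DMSO Input reads and 4.81% of the DMSO J2 reads. They were kept in the sums per gene, which therefore measure mostly non-exonic, largely intronic, RNA and not mature transcripts. Single genes can depart from this. A region on the opposite strand overlapped 80.0% of the regions of the Input table and 79.1% of those of the J2 table.

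Counts were scaled to the library's summed count (CPM). Each region was assigned to a gene of GENCODE release 29 when it overlapped 1 annotated gene on the same strand by any length, and the region counts were summed per gene. A long region can thus bring sequence outside a gene into its sum. Counts were also summed per repeat class, family and subfamily, per annotation, and per place relative to genes (sense, antisense or outside), with place set by any overlap too. For comparisons of J2 with Input, regions of the 2 tables were matched one to one on the same strand by a reciprocal overlap of at least 90%, which gave 158843 pairs; sums over genes and repeats used all regions of each table. Those sums depend on how much sequence each table covers, and the covered length is given beside repeat families for that reason.

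With 1 library per group no test across replicates exists, and no p-value was computed. A region, gene or subfamily was called higher or lower when its counts in the libraries compared summed to at least 50, the ratio of CPM was at least 2-fold, and the exact (Clopper-Pearson) 95% counting interval of the ratio excluded 1. The change of J2 enrichment was the ratio of J2 over Input in MPS1i to that in DMSO, with a 95% delta-method interval on the 4 counts plus 0.5, a minimum of 50 in the J2 pair and 20 in the Input pair, and the same fold and interval rule. Log2 ratios of single genes are the ratios of counts with a pseudocount of 0.5 per library. Intervals of shares are Wilson 95% intervals. A count of 0 was replaced by a floor of 3 counts per library wherever a fold against it is given, and such folds are written as lower bounds.

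Fixed before the data were examined were the 5 comparisons, the thresholds, the alternatives unless said otherwise, the rule for named items, and 21 gene lists with 491 genes. The lists are interferon-stimulated genes, RNA sensing, DNA sensing, inflammatory cytokines and NF-κB targets, p53 targets, mitosis and G2/M, S phase and replication, replication-dependent histones, mitochondrially encoded genes, structured noncoding RNAs, nuclear long noncoding RNAs, genes with inverted Alu repeats in the 3' UTR, KRAB zinc fingers, antigen presentation, integrated stress and unfolded protein response, autophagy and lysosome, ribosomal proteins, housekeeping genes, and markers of lung epithelium, fibroblasts and leukocytes. For each list the number of members past the rule, the median log2 ratio of measured members, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins were computed. The percentile is a description of these libraries and no test of the conditions. The assumption was made that features could be genes, repeat copies or regions; they turned out to be regions.

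The named items were the 5 higher and 5 lower regions, and the 10 higher and 10 lower repeat subfamilies and gene symbols per comparison whose interval bound nearest to 1 lay farthest from 1. Members of the fixed lists and repeat classes with the most reads or past the rule were named as examples. Many of the subfamilies selected were simple repeats of short motifs, and of these only the number is given. AC079949.2, MT-ND5 and TUBB4B ranked among the named genes of J2 against Input but had no region in one of the tables, so no ratio is given for them there. Genes of multigene families that share sequence (IFIT, OAS, histone, zinc finger and ribosomal protein genes, FAM66A) and overlapping genes are uncertain, because reads may be split between copies.

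The calling was tested on simulated counts drawn from the real means and depths. With counting noise alone, 93% of genes changed 2.5-fold and 100% of genes changed 4-fold were recovered in J2 MPS1i against DMSO (10857 genes), and 0.188% of unchanged genes were called. With extra noise of a fixed size per library, not fitted to these data, 68% of 2.5-fold changes in either table and 90% of 4-fold changes in Input were recovered. Under that noise 12.4% of unchanged genes in J2 and 13.1% of unchanged genes in Input (9895 genes) were called. For the change of J2 enrichment (10566 genes), run with counting noise alone, 79% of 2.5-fold and 97% of 4-fold changes were recovered.

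Alternatives were edgeR's TMM factors, DESeq2's median-of-ratios factors and the upper quartile in place of CPM; leaving out rRNA, 7SL, 7SK, snRNA, tRNA and mitochondrial regions; leaving out the 100 most-read regions; count minimums of 200 and of 1 read; a fold of 1.5; a pseudocount of 5; thinning all libraries to the shallowest; and sums per repeat subfamily. An overlap of 50%, a fold met in each of 2 random sets of a gene's regions, sums per the tables' own gene names, and counting each region once were added after seeing the data. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, bedtools 2.31.1, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, the last pair for scaling factors only.

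Depth was 6381610 counts for DMSO Input, 4844956 for MPS1i Input, 9793355 for DMSO J2 and 6697479 for MPS1i J2. The level that 0 counts allow was 0.470, 0.619, 0.306 and 0.448 CPM in the same order. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Between 2 random sets of a gene's regions, log2 ratios varied more than counting error. Their variance was 3.81 to 19.6 times that of counting in Input and 2.14 to 15.4 times in J2, highest for genes with the most reads. This includes real differences between the regions of a gene, but the intervals may be much too narrow.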

Results

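RNA bound by the dsRNA antibody J2 and total RNA (Input) were sequenced from NCI-H1944 lung adenocarcinoma cells that had been exposed to the MPS1 inhibitor BAY-1217389 (100 nM, 48 h, then 24 h without drug) or to DMSO. MPS1 is a kinase of the spindle assembly checkpoint, which delays chromosome separation until all chromosomes are attached to the spindle. Each of the 4 groups held 1 library, so no difference below has a replicate check and each compares libraries, not conditions. Summed counts were 6381610 for DMSO Input, 4844956 for MPS1i Input, 9793355 for DMSO J2 and 6697479 for MPS1i J2. Reads were counted in stranded regions that lay almost entirely outside annotated exons, so a gene's value is mostly the sum of intronic and other non-exonic regions. The 100 most-read regions held 31.3% of the DMSO Input reads, 29.4% of the MPS1i Input reads, 7.74% of the DMSO J2 reads and 8.47% of the MPS1i J2 reads. Mitochondrial RNA took 24.3% and 20.2% of the Input libraries but 0.608% and 0.836% of the J2 libraries, DMSO first. Regions with at least 1 read numbered 940751 in DMSO Input and 484849 in MPS1i Input, and after thinning to equal depth they still numbered 826523 and 484849. The MPS1i Input library thus spread over fewer regions at equal depth, which limits every ratio that uses it. The J2 libraries had reads in 1208576 (DMSO) and 1176736 (MPS1i) regions, and in 881903 and 998387 at equal depth, so MPS1i J2 spread over more regions. Values are log2 ratios of CPM (counts scaled to the summed count of the library) with a 95% counting interval in brackets. An item was called higher or lower at 2-fold or more with at least 50 counts and an interval excluding 1.

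The first comparison asked which dsRNA-forming transcripts differ after a pulse of MPS1 inhibition, the stated aim of the series, by setting J2-bound RNA of MPS1i cells against that of DMSO cells. Interferon-stimulated genes, the antiviral program that cells switch on after sensing foreign or misplaced nucleic acid, were higher in MPS1i J2 throughout. All 35 measured members were called higher, with a median log2 ratio of 3.31, which lay at the percentile 100 of 10000 random lists matched on expression. IFIT1, which binds RNA lacking the normal cap, was at 4.85 [4.37, 5.41], from 34 counts in DMSO to 679 in MPS1i. MX1, a GTPase that blocks virus replication, was at 3.54 [3.21, 3.91]. The ubiquitin ligase pair PARP9 and DTX3L was at 2.75 [2.67, 2.84] and 2.25 [2.17, 2.33]. The lowest of the list was IFI35 at 1.04 [0.25, 1.87].

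Sensors and adaptors of double-stranded RNA went both ways in J2, with 6 of 19 measured members called higher and 4 lower and a median of 0.28 (percentile 99.5). The higher ones were the cytoplasmic RNA helicases DDX58 (RIG-I) at 3.48 [3.29, 3.69], IFIH1 (MDA5) at 3.25 [3.09, 3.42] and DHX58 at 5.35 [3.75, 8.73]. The kinase EIF2AK2 (PKR) was at 1.26, the ubiquitin ligase TRIM25 at 1.29 and the mitochondrial exoribonuclease PNPT1 at 1.52. Among the lower ones were MAVS, the adaptor through which RIG-I and MDA5 signal, at -1.60, the kinase TBK1 at -1.44 and the adaptor TICAM1 at -1.11. ADAR, which edits adenosines in dsRNA, was at 0.28 and did not pass. Of 3 measured DNA sensing genes, IFI16 (3.13) and the nucleotide hydrolase SAMHD1 (2.06) were higher, and CGAS, the cytosolic DNA sensor, was lower at -1.06 [-1.21, -0.91]. Antigen presentation genes were higher in 6 of 7 cases (median 2.05, percentile 99.2). B2M, the light chain of MHC class I, was at 2.82 [1.96, 3.90], the immunoproteasome subunit PSMB9 at 3.06 and CD274 (PD-L1) at 2.74. Inflammatory and NF-κB genes were higher in 4 of 7 cases and lower in 0 (median 1.65, percentile 99.6). The neutrophil chemokine CXCL8 was at 2.19 and TNFAIP3, a brake on NF-κB, at 2.21.

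Cell cycle genes went the other way in J2. Of 28 measured mitosis genes 13 were lower and 1 was higher, with a median of -0.96 (percentile 0.06). The checkpoint kinase BUB1B was at -2.28 [-2.61, -1.97], the spindle protein DLGAP5 at -2.05, the mitotic kinase PLK1 at -2.01 and cyclin B2 (CCNB2) at -1.80, while the checkpoint protein MAD2L1 was higher at 1.56 [0.97, 2.20]. TTK, the gene of MPS1 itself, was at -0.36 and did not pass. Of 23 replication genes 11 were lower and 0 higher (median -0.86, percentile 0.58). UHRF1, which maintains DNA methylation, was at -2.87 [-3.31, -2.48], the replication fork factor CDC45 at -2.35 and the helicase subunit MCM5 at -2.22. Of 15 p53 targets 4 were higher and 0 lower (median 0.14, percentile 85.6). The cell cycle inhibitor CDKN1A (p21) was at 3.04 [2.15, 4.16], the ribonucleotide reductase subunit RRM2B at 1.54, the DNA repair factor XPC at 1.33 and cyclin G1 (CCNG1) at 1.12. Histone genes, whose reads may be shared among near-identical copies, were higher in 5 of 7 cases (median 1.36, percentile 98.9), for example HIST1H2BD at 1.96.

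KRAB zinc finger genes, many of which silence transposons, were lower in 7 of 16 cases and higher in 0 (median -0.82, percentile 0.89), with ZNF43 at -2.01 and ZNF850 at -1.62. Genes carrying inverted Alu pairs in the 3' UTR, a known source of intramolecular dsRNA, were lower in 6 of 26 cases and higher in 2 (median -0.42, percentile 32.3). Their counts come mostly from outside exons, so they do not measure the 3' UTR pairs. The remaining lists had few calls. Stress response genes were higher in 1 of 8 and lower in 2, with the transcription factor ATF3 at 2.17 and the pseudokinase TRIB3 at -1.58 (median -0.32, percentile 30.8). Autophagy genes were higher in 1 of 12 and lower in 3 (median -0.14, percentile 68.5, and 0.11 after thinning to equal depth), with the autophagy receptors OPTN at 1.41 and SQSTM1 (p62) at -1.39. Ribosomal protein genes were higher in 1 of 12 and lower in 4 (median -0.77, percentile 4.68), housekeeping genes higher in 0 of 10 and lower in 2 (median -0.41, percentile 47.8), and lung epithelial markers were called neither way in all 5 measured (median -0.22, percentile 47.7). The nuclear noncoding RNAs PVT1 (-0.75), FTX (-0.62) and SNHG5 (0.14), and MT-ND5 (-0.50), the only measured mitochondrial gene, did not pass. No structured noncoding RNA and no leukocyte marker reached 50 counts as a gene, and the only measured fibroblast marker, the surface protease FAP, was higher at 4.02 [3.43, 4.73].

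Among all 10857 genes measured in J2, 1724 were higher and 2148 lower in MPS1i, with a median of -0.21, and of 36852 regions 4577 were higher and 9900 lower. By the conservative bound the leading gene was SLC16A12-AS1, an antisense transcript at chromosome 10 from 89456064 to 89468140. It had 0 counts in DMSO and 174 in MPS1i, at least 84.8-fold higher. It was followed by FBXO39, an F-box gene at chromosome 17 from 6776223 to 6797101, at 6.96 [5.86, 8.72], and CMPK2, a mitochondrial nucleotide kinase induced by interferon, at 5.95 [5.24, 6.88] with 14 and 611 counts. The noncoding RNA AC107373.1 (at least 44.8-fold), the membrane skeleton gene ANK1 (at least 40.0-fold) and the multicopy noncoding gene FAM66A (at least 32.2-fold) also had 0 counts in DMSO. MX2, an antiviral relative of MX1, was at 6.21, from 4 counts to 227. NRIR, a noncoding RNA next to CMPK2, was at 5.62, IFIT5 at 6.56 [4.62, 12.45] from 1 count, and AL162414.1 at 5.33. On the lower side were ZNF367 at -3.55 [-4.78, -2.66], UHRF1 and SMAD4, the common mediator of TGF-β signalling, at -3.05 [-3.53, -2.63] with 564 and 46 counts. The ubiquitin ligase adaptor FBXO17 (-2.65), the redox protein NXN (-2.68), the 14-3-3 protein YWHAE (-2.46), the transcription factor NFIC (-2.57), the glycosylation enzyme ALG6 (-2.77), the snRNP import adaptor SNUPN (-2.86) and the recombination gene XRCC2 (-2.46) completed the lower genes.

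The 4 leading regions in J2 lay in a single stretch of chromosome 10 downstream of IFIT1. The region from 89434880 to 89439187 had 4 counts in DMSO and 657 in MPS1i (7.74 [6.54, 9.79]), and the one from 89411882 to 89413766 had 8 and 716 (6.95 [6.05, 8.25]). The region from 89445741 to 89447459 overlapped an L1PA6 element and had 1 and 280 counts (8.10 [6.19, 13.99]), and the one from 89413784 to 89414507, at the start of IFIT5, had 2 and 356 (7.70 [6.16, 11.08]). The fifth, an L1M1 copy at chromosome 7 from 93092409 to 93093578 near SAMD9, had 0 and 138 counts, at least 67.3-fold. At the IFIT locus, sums were taken over regions that passed a minimum count in the DMSO and MPS1i libraries together. On the IFIT strand 64 such regions held 168 J2 reads in DMSO and 7638 in MPS1i (6.05 [5.83, 6.28]). On the opposite strand, where LIPA and SLC16A12 lie, 7 such regions held 110 and 351 (2.22 [1.91, 2.54]). Regions with few reads were left out, so these are not all reads of the locus. Regions high in MPS1i pass the minimum more easily, so the ratios may be too high. The IFIT genes resemble each other, so reads may be split between them. The lower regions were intronic and had 0 counts in MPS1i. They were an AluJo in ACACA (chromosome 17, 37347127 to 37347524, at least 17.3-fold lower) and intervals in YWHAE (chromosome 17, 1371012 to 1371342, at least 17.1-fold), ORC3 (chromosome 6, 87600044 to 87601296, at least 14.6-fold), SERINC5 (chromosome 5, 80187245 to 80188067, at least 13.7-fold) and AMBRA1 (chromosome 11, 46540656 to 46541294, at least 13.5-fold).

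**Figure D1:**
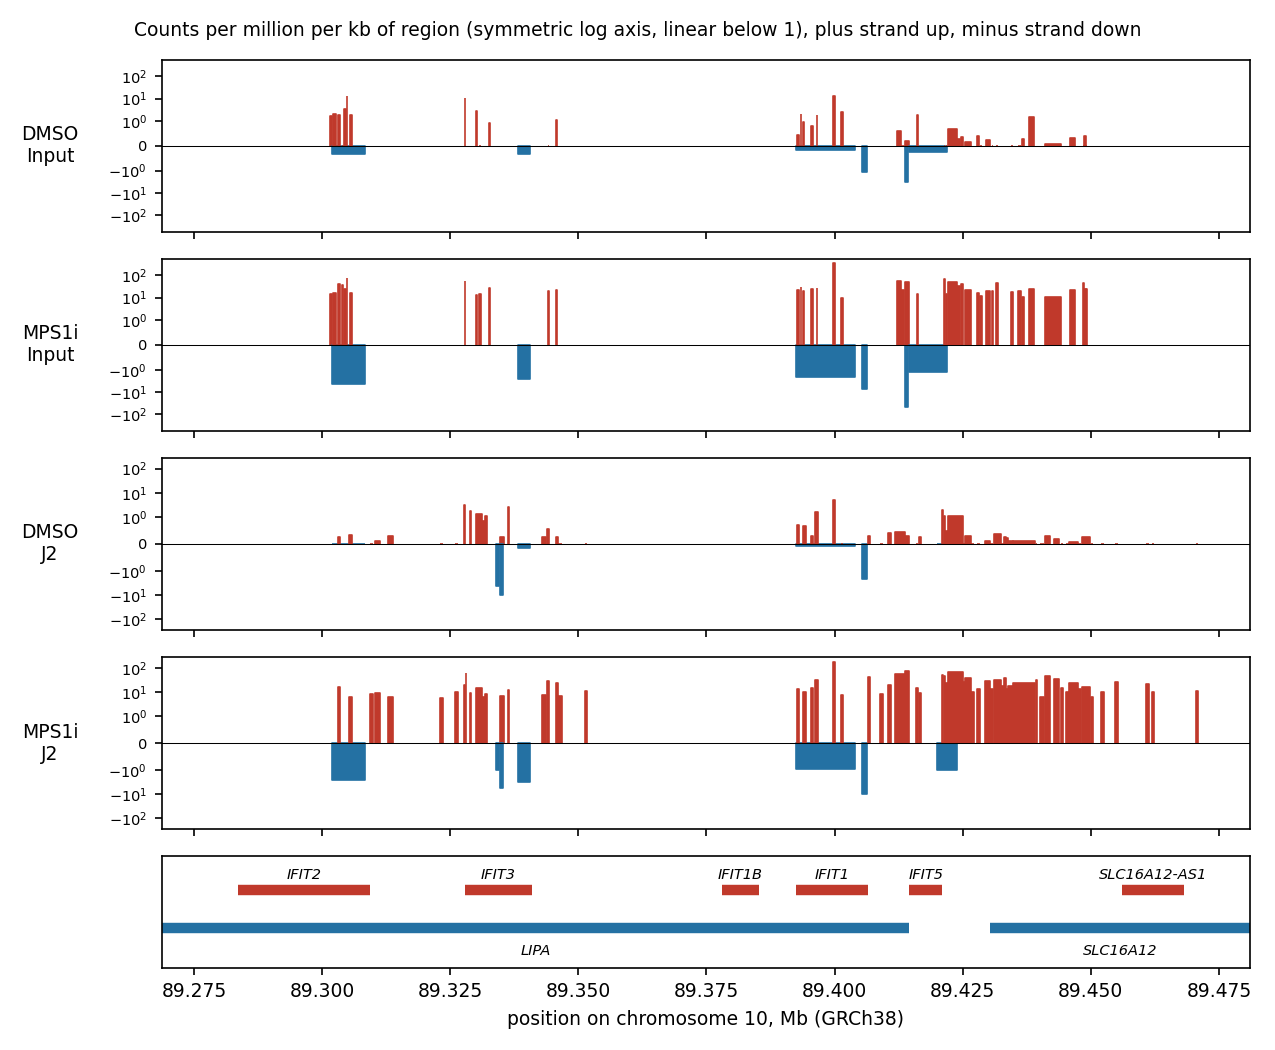
CPM per kb of region (symmetric log axis) along chromosome 10 from 89268694 to 89481001 (GRCh38, axis in Mb) in the 4 libraries, with plus-strand regions drawn up in red, minus-strand regions drawn down in blue and annotated genes at the bottom; there are no error bars. Plus-strand counts were summed over regions that passed a minimum count in the DMSO and MPS1i libraries of their table together. These sums, which leave out regions with few reads, were 125 in DMSO Input and 3220 in MPS1i Input. In J2 they were 168 in DMSO and 7638 in MPS1i. Reads continued past the annotated end of IFIT5.

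Repeat families differed less than these genes, and none of the large families reached 2-fold in J2. Alu elements, short primate retrotransposons whose inverted copies can fold into dsRNA, were lower in MPS1i J2 at -0.34 [-0.35, -0.34], and between -0.31 and -0.39 under the other scalings. L1, the only retrotransposon family that still moves on its own in humans, was higher at 0.20 [0.19, 0.20], and between 0.15 and 0.23 under the other scalings. The young L1HS and L1PA copies were at 0.55 and the L1PB copies at 0.64. Endogenous retroviruses on the strand of the region were higher, with ERV1 at 0.44, ERVL at 0.29, ERVL-MaLR at 0.23 and ERVK at 0.09. By HOMER's annotation, which names copies on either strand, they were at 0.08, 0.10, 0.02 and -0.23 in the same order, Alu at -0.22 and L1 at 0.06. The centromeric ALR/Alpha satellite was at 0.83 [0.73, 0.93] from 1629 and 1980 counts. SVA was at 0.07, L2 at -0.08, DNA transposons at -0.07, simple repeats at 0.00, low complexity sequence at 0.28, and MIR at -0.02, which turned to 0.01 with the upper quartile. Of the structured RNA classes, scRNA was at -0.92 and srpRNA at 0.31. Of 1402 subfamilies 135 were higher and 85 lower. The leading ones besides simple repeats were the retroviral LTR23-int at 3.56, HERV9N-int at 2.83 [2.39, 3.31] with 49 and 240 counts, HERV9-int at 2.74, MER76-int at 2.74, LTR24 at 2.44 and HERV3-int at 2.32, and the L1 subfamilies L1M2a1 at 3.31 and L1M6B at 1.96. Lower were HY1, a Y RNA family, at -1.68 [-1.90, -1.48] with 1049 and 223 counts, and the DNA transposon Charlie1b at -1.50. Another 2 of the 10 leading higher subfamilies and 8 of the 10 leading lower ones were simple repeats.

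The direction of a repeat family depended on where its copies lay. Alu in J2 was at -0.56 in regions overlapping genes on the gene's strand, at 0.23 in those overlapping genes on the opposite strand and at 0.14 outside genes, and L1 was at -0.27, 0.97 and 0.67. Regions without a repeat were at -0.21, 0.71 and 0.61 at the same places. Reads on the strand of genes made up 70.6% of the DMSO J2 library and 58.95% of the MPS1i J2 library, and reads outside genes 19.62% and 27.01%. With 1 read per region counted at most, 415 genes were higher and 1032 lower in place of 1724 and 2148, and 1331 and 1513 reached 2-fold in each of 2 random sets of their regions.

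**Figure D2:**
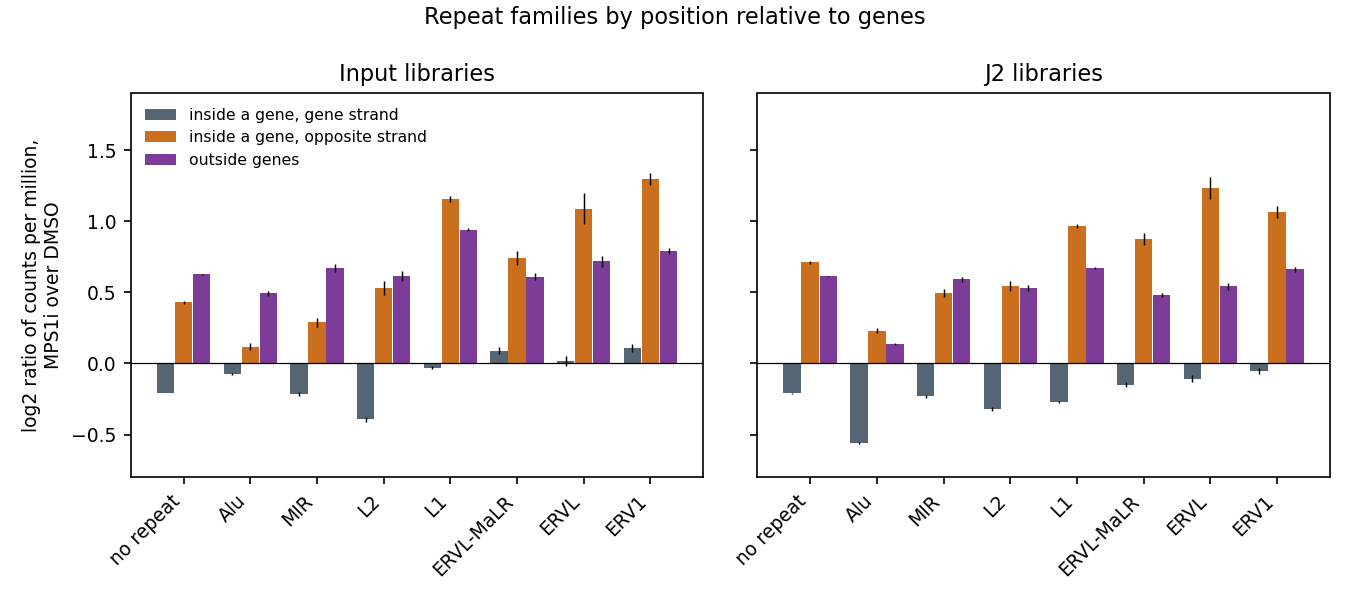
Log2 ratios of CPM (MPS1i over DMSO) of repeat families and of regions without a repeat in the Input libraries (left) and the J2 libraries (right). Bars are for regions overlapping a gene on its strand, overlapping a gene on the opposite strand, and outside genes, and lines for 95% counting intervals. In J2 all 8 sets were below 0 on the gene strand (Alu -0.56) and above 0 elsewhere (L1 0.97 antisense), and in Input the bars near 0 change sign with the scaling, among them gene-strand Alu (-0.07), L1 (-0.03), ERVL (0.02) and ERV1 (0.11) and antisense Alu (0.12), MIR (0.29) and no repeat (0.43).

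The Input libraries gave the background, the same comparison in total RNA. Interferon-stimulated genes were again higher in MPS1i, all 36 measured of 42 listed, with a median of 3.08 (percentile 100). The count minimum favours members high in MPS1i here too. MX2 was at 8.01 [6.10, 13.90] with 1 and 293 counts, IFIT1 at 4.58 [4.16, 5.06] with 45 and 824, RSAD2, the antiviral enzyme viperin, at 5.70, CMPK2 at 5.09, MX1 at 3.09, ISG15, a ubiquitin-like modifier, at 3.21 and OAS1, a dsRNA-activated synthetase with close relatives, at 2.43. Mitosis genes were lower, 17 of 29 with 0 higher (median -1.27, percentile 0.00), including the anaphase activator CDC20 at -3.37 [-5.90, -1.94], cyclin B1 (CCNB1) at -2.58 [-3.22, -2.03], the spindle protein ASPM at -2.13, topoisomerase TOP2A at -2.02 and TTK at -1.27 [-1.88, -0.72].

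RNA sensing genes were higher in 7 of 18 and lower in 2 in Input (median 0.44, percentile 99.97; the median was -0.00 with TMM factors). DDX58 was at 3.67 [3.48, 3.86], IFIH1 at 2.67, EIF2AK2 at 1.60, ZC3HAV1, an antiviral protein that binds CpG-rich RNA, at 1.32 and ADAR at 1.27, while MAVS was at -1.01. The 3 measured DNA sensing genes had the same calls as in J2 (IFI16 2.44, SAMHD1 2.02, CGAS -1.09). Antigen presentation genes were higher in 4 of 6 (median 1.85, percentile 99.96), with B2M at 2.69 [2.09, 3.38] and the peptide loading factor TAPBP at 1.98. Inflammatory genes were higher in 5 of 8 (median 1.41, percentile 95.7), with the chemokine CCL5 at 3.20 [2.15, 4.67] and TNFAIP3 at 3.34. Of 17 p53 targets 4 were higher and 0 lower (median 0.80, percentile 99.9). The antiproliferative gene BTG2 was at 3.04, CDKN1A at 2.23 [1.70, 2.83], the stress cytokine GDF15 at 2.14 and SPATA18 at 1.39. Replication genes were lower in 9 of 24 and higher in 1 (median -0.82, percentile 0.11), with CDC45 at -4.61 [-6.18, -3.57] and MCM6 at -2.93 against cyclin E2 (CCNE2) at 2.12. Histone genes were higher in 6 of 7 (median 1.49, percentile 98.95).

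In the other lists calls were few in Input. Stress genes were higher in 1 of 9 and lower in 1, with ATF3 at 3.35 and TRIB3 at -1.17 (median -0.50, percentile 20.2). Autophagy genes were higher in 3 of 12 and lower in 1 (median 0.03, percentile 68.9), with OPTN at 2.63. KRAB zinc finger genes were lower in 1 of 9, ZNF431 at -1.75 (median -0.39, percentile 32.0), and inverted Alu genes lower in 4 of 23 and higher in 1 (median -0.32, percentile 51.7). Ribosomal protein genes were lower in 2 of 17, RPL32 at -1.70 and RPL13A at -1.56 (median -0.53, percentile 9.87). Of 15 housekeeping genes the glycolytic enzyme TPI1 was higher at 2.94 and 0 were lower (median -0.34, percentile 44.7). The 5 lung epithelial markers and the 3 nuclear noncoding RNAs did not pass (median of the markers 0.07, percentile 83.0), and FAP was at 3.71 [2.99, 4.63].

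Of 9895 genes measured in Input, 1261 were higher and 1656 lower, with a median of -0.23. Besides MX2, FBXO39 (5.73), RSAD2 and CMPK2, the higher genes by the conservative bound were the noncoding RNAs LINC01285 at 6.65 [5.31, 9.16], AC073365.1 at 6.66 [4.74, 12.56] and LINC01886 at 5.78 [4.21, 9.16], and the interferon-induced TRIM22 at 5.65. C3orf85 and the adhesion receptor gene ADGRF2 had 0 counts in DMSO and were at least 31.2-fold and 23.7-fold higher. The lower genes besides CDC45, MCM6 and SMAD4 (-3.17) were the microRNA processing factor DGCR8 at -4.31 [-6.09, -3.18], the centrosomal gene CEP78 at -3.63 and DBT, a subunit of branched-chain amino acid breakdown, at -3.12. HEATR6 was at -3.32, FLAD1, which makes the cofactor FAD, at -3.59 [-6.12, -2.18], NCLN at -3.32 and the tRNA-modifying CTU1 at -2.79. Of 16957 regions 2729 were higher and 2391 lower. Leading among them were 4 regions at the IFIT locus on chromosome 10, from 89413815 to 89414563 with 1 and 180 counts (7.31 [5.39, 13.20]), from 89441078 to 89444099 with 1 and 152, from 89422223 to 89423832 with 7 and 384, and from 89412140 to 89412922 with 3 and 200. Another lay antisense to MX2 (chromosome 21, 41376973 to 41409514, 1 and 146 counts, 7.01 [5.09, 12.90]). The lower regions lay in introns of ITPR1 (chromosome 3, 4685766 to 4686388, at least 19.5-fold), ASS1 (chromosome 9, 130495647 to 130496258, at least 18.2-fold), GIGYF2 (chromosome 2, 232793086 to 232794029, at least 17.7-fold) and AKR1C2 (chromosome 10, 4990059 to 4990967, 341 and 10 counts, -4.63 [-5.77, -3.80]), and at the end of SNHG16 (chromosome 17, 76561776 to 76562443, 109 and 1 counts, -5.79 [-11.69, -3.86]).

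**Figure D3:**
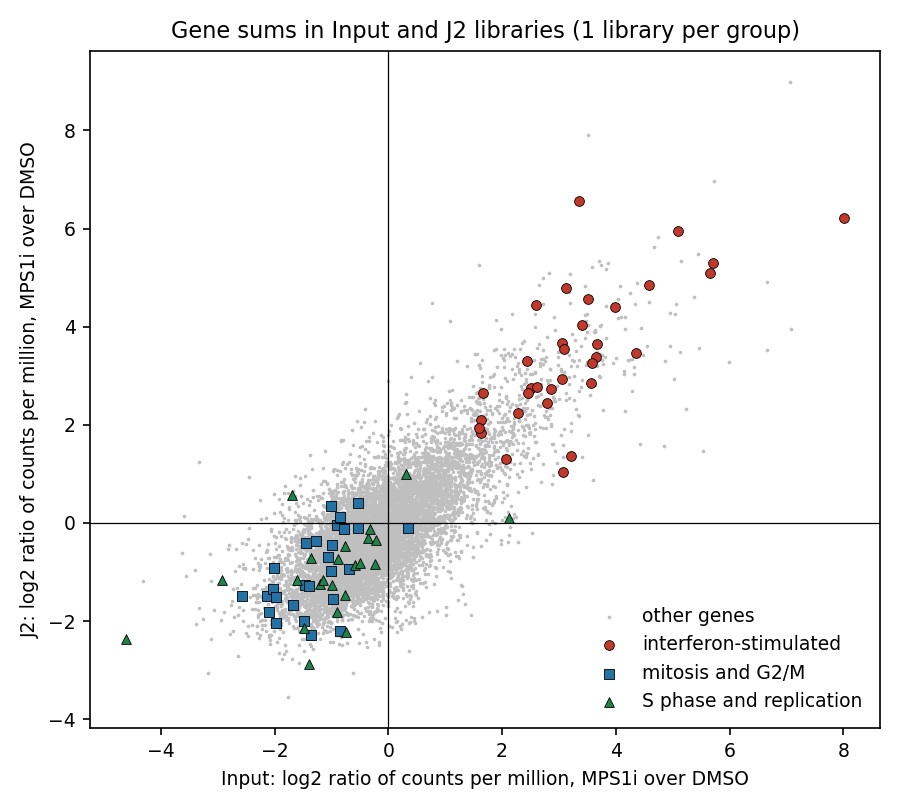
Log2 ratios of CPM (MPS1i over DMSO) of 9339 genes in the Input libraries (horizontal axis) and the J2 libraries (vertical axis), 1 point per gene without error bars, with 3 fixed lists in colour. All 33 interferon-stimulated genes measured in both lay above 0 on both axes, and 23 of 27 mitosis genes and 20 of 23 replication genes lay below 0 on both.

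Repeat families in Input depended on scaling. L1 was at 0.45 [0.44, 0.45] by CPM and at -0.00 with TMM factors, ERVL at 0.41 (-0.04 with TMM), ERVL-MaLR at 0.40 (-0.05) and ERVK at 0.24 (-0.20). Alu was at 0.04, at -0.41 with TMM and at 0.22 with the upper quartile. ERV1 at 0.67, the young L1HS and L1PA copies at 0.87, LTR12, a retroviral promoter family, at 1.10 and ALR/Alpha at 1.25 [1.05, 1.45] were higher by CPM and stayed above 0 under the other scalings, which moved all values alike by at most 0.45. Of 1182 subfamilies 145 were higher and 42 lower, with HERV9N-int at 3.22 [2.55, 4.02], MER84 at 3.36, HERV9-int at 2.62, HERVP71A-int at 2.19, L1PBa1 at 2.06, LTR75 at 2.20, LTR12E at 2.21, LTR12D at 2.02 and the satellite BSR/Beta at 2.36 on the higher side. On the lower side were Charlie26a at -3.42, LTR65 at -2.71, HY1 at -2.15 [-2.60, -1.74] with 323 and 55 counts, and HERVK13-int at -1.83. The scaling shifted the median of all genes in Input by -0.45 with TMM factors, -0.40 with median-of-ratios factors and 0.19 with the upper quartile. Genes called higher and lower were then 790 and 3390, 827 and 3164, and 1547 and 1094, so the share of higher calls was 18.9%, 20.7% and 58.6% against 43.2%. For regions the share of higher calls was 26.1%, 28.6% and 65.8% against 53.3%. When each region counted at most once, 91 genes were higher and 993 lower.

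Changes in J2 went with changes in Input. Across the 9340 genes measured in both, the log2 ratios had a Spearman correlation of 0.69 and a Pearson correlation of 0.77, across genes that are not independent replicates. Of the genes called higher, 797 were shared, where independent lists would share 143, and of those called lower 892, where independent lists would share 326. Only 5 genes higher in J2 were lower in Input, and 10 lower in J2 were higher in Input.

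J2-bound RNA was next set against Input within DMSO cells, to describe what the antibody enriched without drug. Alu sequence took a larger share of J2 counts than of Input counts at 0.81 [0.80, 0.81], but the J2 regions covered 40487 kb of Alu and the Input regions 21427 kb, and per covered kb the ratio was -0.11. For L1 it was 0.50 over 55871 and 32870 kb, or -0.26 per covered kb. Regions without a repeat were at -0.38, or -1.04 per covered kb, so Alu and L1 lay above them by either measure. Genes with inverted Alu pairs in the 3' UTR were counted mostly outside exons, so their sums do not measure those pairs. Of these genes 12 of 25 were higher in J2 and 2 lower (median 0.95, percentile 99.7). They included MDM2, the ubiquitin ligase of p53, at 1.91 [1.83, 1.99], the carboxylase subunit PCCB at 1.89, MAVS at 1.62 and the zinc finger gene ZNF83 at 1.84. KRAB zinc finger genes were higher in 8 of 17 and lower in 0 (median 0.88, percentile 99.4). At the other end, the counted regions of some genes were depleted, such as those of the ribosomal protein gene RPS6 at -10.46 [-11.35, -9.79], GAPDH at -7.11 [-8.08, -6.39] and the actin gene ACTB at -4.21. Whether these counts lay in exons was not examined.

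Autophagy genes were also higher in DMSO J2, 7 of 12 with 1 lower (median 1.10, percentile 99.7), for example the lysosomal protease CTSB at 2.61. Ribosomal protein genes were higher in 5 of 16 and lower in 7 (median -0.19, percentile 1.02, 0.21 with the upper quartile), and housekeeping genes higher in 3 of 14 and lower in 6 (median -0.41, percentile 0.09). Stress genes were lower in 2 of 9 (median -0.79, percentile 0.35), with the stress transcription factor XBP1 at -3.18, and lung epithelial markers higher in 1 of 6 and lower in 3 (median -0.88, percentile 0.20) with the keratin KRT18 at -8.94. Interferon-stimulated genes went both ways, 5 of 21 higher and 5 lower (median 0.07, percentile 24.8), with SAMD9L at 3.24 and OAS1 at -1.21. Mitosis genes were higher in 7 of 29 and lower in 5 (median 0.33, percentile 31.2), among them cyclin A2 (CCNA2) at 4.05 and the cytokinesis factor ECT2 at 2.08. Replication genes were higher in 7 of 24 and lower in 7 (median 0.01, percentile 3.26). RNA sensing genes were higher in 3 of 19 and lower in 2 (median 0.52, percentile 66.8), with TRIM25 at 2.96 and the helicase DHX9 at -1.76, and p53 targets higher in 5 of 14 and lower in 3 (median 0.28, percentile 45.7).

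By the conservative bound the genes highest in DMSO J2 over Input were TIMM8A, a mitochondrial import chaperone, with 1880 and 0 counts (at least 408-fold), FAM8A1 at 9.32 from 3 Input counts, the cell cycle kinase CDK4 at 8.64 [6.74, 14.53] from 1 Input count, the histone chaperone ANP32E at 7.01 and ZNF669 at 8.11 [6.21, 14.00]. AC007620.2 (at least 78.6-fold), the secreted phosphoprotein SPP1 at 6.53 and AL591721.1 at 7.04 [5.71, 9.54] followed. For AL591721.1 the J2 regions covered 42.115 kb and the Input regions 0.55 kb, which makes up most of its ratio, and for CDK4 they covered 3.632 and 0.72 kb. The lowest besides RPS6 and KRT18 were the histone chaperone SET at -9.29, RPS14 at -10.44 [-13.80, -8.90], RPL4 at -9.02, MRPL50 at -8.97, POLR3D at -8.73, TMSB10 at -7.81, C9orf78 at -8.70 and RPL7A at -8.68. Among matched regions an interval over the small nucleolar RNA SNORA47 (chromosome 5, 77061232 to 77061703) had 11615 counts in J2 and 33 in Input, 7.82 [7.35, 8.38]. Intronic intervals of TOMM70 (chromosome 3, 100368167 to 100368304, 1146 and 1 counts, and 100369136 to 100369497, 369 and 0), CPS1 (chromosome 2, 210650439 to 210650581, 976 and 1) and XPOT (chromosome 12, 64425910 to 64426039, 973 and 2) followed. Depleted were intervals in AKR1C1 (chromosome 10, 4963533 to 4963789, 12 and 7024 counts) and beside PTP4A1 (chromosome 6, 63579342 to 63580033, 39 and 4298), and the small nuclear and cytoplasmic RNAs RN7SK (chromosome 6, 52995622 to 52995936, 34 and 7910) and RN7SL3 (chromosome 14, 49853529 to 49853919, 23 and 3722).

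In DMSO 2050 genes of 10339 were higher in J2 and 1039 lower (median 0.35), of which 13 of the higher had no region in the Input table and 7 of the lower none in the J2 table. The counts were 1883 and 1418 for 8159 matched regions and 335 and 118 for 1374 subfamilies. Among families, L2 was at 0.59 (16687 kb in J2 and 10216 kb in Input), MIR at 0.31 (16823 and 10538 kb), ERVL-MaLR at 0.71 (11567 and 6123.5 kb) and ERVK at 0.69 (1234.1 and 758.27 kb), and all were below 0 per covered kb, at -0.12, -0.37, -0.21 and -0.014. ALR/Alpha was at 1.71 [1.54, 1.89] over 3223.9 and 1130.4 kb, or 0.20 per covered kb. ERV1 was at -0.33 over 8152.5 and 4884 kb (0.07 with the upper quartile), HERVH-int, a retrovirus expressed in stem cells and some tumours, at -1.64 over 680.1 and 768.76 kb, and regions without repeat at -0.38 over 346530 kb in J2 and 218580 kb in Input. Promoter regions were at -3.43, but this class was not separated from mitochondrial reads, which were at -5.32, so the value does not describe promoters as such. The leading subfamilies were simple repeats apart from tRNA-Ser-TCA(m) at 7.15 [5.25, 13.04] and tRNA-Leu-TTA(m) at -5.77, whose reads came from a mitochondrial rRNA region. The scalings shifted the median by 0.14 (TMM), 0.11 (median-of-ratios) and 0.40 (upper quartile), and the upper quartile gave 3827 genes higher and 686 lower, or 84.8% higher against 66.4%, and for regions 75.0% against 57.0%. Mitochondrial reads took 24.3% of DMSO Input and 0.608% of DMSO J2, which by itself raises the CPM ratios of all other RNA in J2. Leaving out abundant RNAs, mitochondrial regions among them, turned the balance to 953 higher and 1629 lower. An excess of higher items by CPM is therefore no measure of J2 binding.

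In MPS1i cells J2 was set against Input in the same way. Mitosis genes were higher in J2 in 11 of 28 cases and lower in 3 (median 0.78, percentile 99.9), with ECT2 at 3.05 [2.90, 3.20], CCNA2 at 3.60 and CCNB1 at 2.24. Interferon-stimulated genes again went both ways, 7 of 38 higher and 8 lower (median 0.19, percentile 8.22, and -0.13 without abundant RNAs), from SAMD9L at 3.22 [2.94, 3.51] and PARP9 at 1.19 to IFI27 at -3.00 and the membrane protein BST2 at -5.48. Alu sequence was at 0.43 [0.42, 0.44] and L1 at 0.26, or -0.49 and -0.51 per covered kb. Regions without a repeat, again not separated from mitochondrial reads (-4.60), were at -0.97 per covered kb. Outside genes, Alu was at 0.94, L1 at 0.28 and regions without a repeat at 0.29, without regard to covered length. Inverted Alu genes were higher in 8 of 24 and lower in 2 (median 0.66, percentile 93.8), with MDM2 at 2.11, and KRAB zinc finger genes higher in 4 of 11 and lower in 0 (median 0.76, percentile 93.5).

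Antigen presentation genes were lower in 2 of 8 and higher in 1 (median -0.55, percentile 1.43), p53 targets lower in 5 of 18 and higher in 4 (median -0.20, percentile 1.72, 0.15 with TMM), and stress genes lower in 4 of 9 (median -0.66, percentile 0.48). Ribosomal protein genes were lower in 7 of 15 and higher in 2 (median -0.37, percentile 0.36, 0.10 with the upper quartile), housekeeping genes lower in 7 of 15 and higher in 1 (median -0.42, percentile 0.20, 0.04 with the upper quartile) and lung epithelial markers lower in 3 of 5 (median -1.20, percentile 0.06). Named genes on the higher side were CDK4 (1615 and 0 counts, at least 389-fold), TIMM8A (at least 227-fold), the ubiquitin ligase scaffold CUL4B at 7.76 [6.99, 8.83] and FAM8A1 at 7.56. AL591721.1 (at least 81.7-fold), SPP1 at 6.07, LIN7C at 6.10, ANP32E at 6.17 and OIP5, a centromere protein, at 6.17 were also higher. Covered length differed here too, with 42.115 kb in J2 and 0.55 kb in Input for AL591721.1 and 39.647 and 7.365 kb for OIP5. On the lower side were RPS6 at -12.18 [-14.68, -10.86] from 3 J2 counts, SET at -10.89, RPS14 (0 and 2537 counts, at least 1169-fold), RPL4 at -9.12, and MRPL50 at -9.57 [-12.07, -8.24], followed by RPL39 at -8.65, TMSB10 at -7.99, POLR3D at -7.87 and KRT18 at -7.64. The SNORA47 interval had 10873 counts in J2 and 9 in Input, an intronic interval of the transporter ABCC2 (chromosome 10, 99805448 to 99805910) 2111 and 1, and intervals of RN7SL1 (chromosome 14, 49586579 to 49586879) and RN7SL2 (chromosome 14, 49862551 to 49862853) 11 and 1738, and 9 and 1304.

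In MPS1i 1916 genes were higher and 981 lower of 10468 (median 0.30), 14 and 7 of them without a region in the other table, 1484 and 1065 regions of 6291, and 255 and 103 subfamilies of 1276. The median shifted by 0.35 (TMM), 0.15 (median-of-ratios) and 0.47 (upper quartile), with 3361 genes higher and 658 lower under TMM (83.6% higher against 66.1%) and 3919 and 578 under the upper quartile (87.1%), and for regions 75.0% and 78.8% against 58.2%. Mitochondrial reads took 20.2% of MPS1i Input and 0.836% of MPS1i J2, which raises the other CPM ratios here too. Without abundant RNAs 1144 genes were higher and 1479 lower.

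The last comparison divided the ratio of J2 to Input in MPS1i by that in DMSO. It had no control antibody, so RNA carried over without binding J2 is included, and a low count in MPS1i Input raises it. Mitosis genes had a higher enrichment in MPS1i as a list (median 0.45, percentile 99.9), with 5 of 28 called higher and 1 lower. MAD2L1 was at 1.78 [0.76, 2.81], the separase inhibitor PTTG1 at 1.35, CCNB1 at 1.10, the centromere protein CENPF at 1.08 and separase (ESPL1) at 1.05, against the survivin gene BIRC5 at -1.35 [-2.20, -0.50]. Interferon-stimulated genes mostly lay within 2-fold, 4 of 35 higher and 2 lower (median 0.19, percentile 89.7, -0.02 after thinning). IFIT5 was at 3.20 [0.59, 5.81], the ISG15 ligase HERC5 at 3.18 [1.02, 5.35], IFI44L at 1.84 and XAF1 at 1.66 against IFI35 at -2.02 and ISG15 at -1.84 [-2.59, -1.09]. Autophagy genes were lower in 4 of 12 and higher in 1 (median -0.46, percentile 2.81), with SQSTM1 at -1.22 [-1.42, -1.01] and OPTN at -1.22. Alu enrichment was lower by CPM at -0.38 [-0.39, -0.37] and L1 enrichment at -0.25 [-0.26, -0.24], and at -0.17 and -0.036 with TMM factors fitted to all 4 libraries.

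Single genes with the largest conservative differences were, on the higher side, HEATR6 at 4.57 [3.19, 5.94], whose Input counts were 85 and 6, EAF1 at 5.09 [2.62, 7.56] from 1 Input count in MPS1i, SPOPL at 3.38, the RNA-binding HNRNPDL at 3.71, and the phosphodiesterase PDE5A at 4.78 [2.35, 7.21]. The magnesium channel TRPM6 was at 3.57, PSCA at 3.66, CAPRIN2 at 2.75, ZNF32 at 3.24 and the translocon subunit SEC61G at 3.72. On the lower side HNRNPC, a nuclear protein that binds uridine-rich and Alu-derived introns, was at -2.40 [-2.51, -2.29], with 8923 and 8847 counts in Input but 5478 and 924 in J2 (DMSO first). AL139807.1 (-3.83), the ubiquitin-conjugating UBE2G1 (-2.29), CHST12 (-3.33), C8orf76 (-2.64), THAP8 (-3.47), the helicase DDX42 (-2.30), RPL14 (-3.55) and RUVBL2 (-2.50) were also lower. Matched regions on the higher side lay antisense to IDH2 (chromosome 15, 90085283 to 90102340, 5.41 [3.41, 7.41]), PHF19 (chromosome 9, 120857148 to 120877170) and UHMK1 (chromosome 1, 162497821 to 162524061, 3.74). The PHF19 region had 23 and 33 counts in J2 and 48 and 0 in Input (DMSO first), so no ratio is given for it. Others lay in introns of ABCC2 (5.14) and RNF213 (chromosome 17, 80366879 to 80367494, 3.83). On the lower side were introns of SLC35F3 (chromosome 1, 233982712 to 233983125, -4.09), APTX (chromosome 9, 33023609 to 33024174, -3.85) and UBE2R2 (chromosome 9, 33849770 to 33850491, an AluJb, -3.74), an AluJo at chromosome 17 from 205079 to 205714 (-3.95) and an interval in SRFBP1 (chromosome 5, 122038533 to 122038971, -4.00). Subfamilies on the higher side included Charlie26a at 3.75, L1M2a1 at 3.28 and MER70C at 2.37, and on the lower side UCON40 at -3.19, MER127 at -2.77, LTR34 at -2.09, MER61B at -2.07 and MamGypsy2-LTR at -2.40.

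RNA sensing genes were higher in 1 of 19 and lower in 1 (median -0.18, percentile 18.4), inflammatory genes higher in 1 of 6 and lower in 1 (median -0.53, percentile 7.21), and ribosomal protein genes higher in 1 of 11 and lower in 1 (median -0.39, percentile 4.90, 0.08 without the 100 most-read regions). In all, 964 genes were higher and 822 lower of 10566 (median -0.01), 1001 and 649 regions of 7376, and 76 and 92 subfamilies of 1296. TMM factors shifted the median by 0.21 and gave 1474 genes higher and 502 lower, or 74.6% higher against 54.0%, and for regions 75.8% against 60.7%.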

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

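Of the tests below, those of place relative to genes, of GC content in simple repeats and of the Alu strands were chosen after the result was seen, and the test of the L1 strands was written before.

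Alu RNA and L1 RNA parted in both tables, with Alu below L1 by 0.411 in Input and 0.540 in J2. Alu was at -0.34 in J2 and 0.04 in Input, a difference of -0.378 [-0.387, -0.369], and L1 at 0.20 and 0.45, a difference of -0.249 in the same direction. These differences were not tested against replicates, and they depend on scaling. With TMM factors fitted to all 4 libraries the Alu difference was -0.165, and with TMM factors fitted per table Alu was at -0.32 in J2 and -0.41 in Input, which reverses it. Alu copies lie mostly in introns and gene-rich DNA, while L1 copies lie mostly in gene-poor DNA, so the pair reads out where RNA comes from as well as which family it belongs to.

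Place relative to genes, taken only as gene strand, opposite strand or outside, did not account for Alu in J2. Gene density was not matched, so it stays open for Alu. Genes in the densest surroundings had a median of -0.55 in J2 and those in the sparsest 0.24. Against regions without a repeat at the same place in J2, Alu was off by -0.477 outside genes, -0.351 on the gene strand and -0.482 on the opposite strand, and L1 by 0.056, -0.061 and 0.255, so that L1 opposite to genes was not accounted for either. In Input the values were -0.133, 0.136 and -0.312 for Alu and 0.315, 0.180 and 0.728 for L1. Genomic DNA gives both strands alike, and was argued against as the whole cause for L1 by a strand difference outside genes of 0.40 in J2 and 0.70 in Input, although the opposite L1 strand was also higher, at 0.32 and 0.33. For Alu it stays open, with a strand difference of 0.061 [-0.085, 0.207] in J2 and 0.335 in Input. GC content of the fragments stays open, since GC-rich minus AT-rich simple repeats gave 0.027 with a range of -0.16 to 0.22. Genes whose transcripts had the highest GC content had a median of -0.52 in J2 and those with the lowest -0.03, but the GC content of the counted regions was not available.

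Mitochondrial RNA also went apart between the tables. The mitochondrial genome is copied from both strands, and overlapping copies form dsRNA that is normally degraded. Reads of the plus strand were at 0.47 in J2 against -0.26 in Input, a difference of 0.732, and those of the minus strand at 0.34 against -0.82, a difference of 1.16. These differences were not tested against replicates. The minus strand made up 0.818% of mitochondrial reads in DMSO Input and 8.54% in DMSO J2, and 0.558% and 7.88% in MPS1i. The minus strand was thus carried over into J2 far more than the plus strand in either condition, and what raised both relative to Input in MPS1i stays open.

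Among small structured RNA classes, without a test against replicates, 2 stood out. The tRNA class was at 0.60 in J2 and -0.34 in Input, a difference of 0.947, but most of its reads came from 1 mitochondrial interval at the rRNA genes, so it repeats the mitochondrial result and not one of nuclear tRNA. The snRNA class, RNAs of the spliceosome, was at -0.22 in J2 and 0.22 in Input, a difference of -0.442 [-0.631, -0.253], but with TMM factors fitted per table it was at -0.20 in J2 and -0.23 in Input, so the difference rests on the scaling.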

How the results depend on the processing

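Leaving out a replicate could not be run, since each group held 1 library. No paired analysis was possible because each condition gave 1 pair of J2 and Input libraries, without a repeat of the pair. A run on genes outside multigene families was not made as such because the items are regions, and sums per repeat subfamily were run instead. An overlap of 50%, 2 random sets of regions, sums per gene name of the tables and each region counted once were chosen after the data were seen. Of 208 values of list sizes 107 moved, and the balance of higher and lower turned under at least 1 setting in every comparison. Of 750 values of named items 23 moved and all kept their sign, and of 42 values of the leading gene lists 1 moved. Of 466 values of the other lists 17 moved and 420 kept their sign. Of 24 values of the leading repeats 17 moved and 19 kept their sign, and of 641 values of the other repeats 410 moved and 596 kept their sign. The percentile of interferon-stimulated genes stayed at 100 under every alternative for both MPS1i comparisons. Depth of 1 library limits the rest, and 44.7% of the regions with a read in DMSO Input, 27.7% in MPS1i Input, 39.5% in DMSO J2 and 48.0% in MPS1i J2 had only 1 read. Where values moved the cause was not tested.

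With TMM factors, Input MPS1i against DMSO gave 1505 regions higher and 4255 lower and 790 genes higher and 3390 lower, J2 against Input in MPS1i gave 2289 regions and 3361 genes higher, and the change of J2 enrichment gave 1474 genes higher and 502 lower. Alu was at -0.32 and L1 at 0.22 in J2, Alu at -0.41 and L1 at -0.0013 in Input, and the mitosis list at -1.72 in Input. With median-of-ratios factors Input MPS1i against DMSO gave 1608 regions higher and 4008 lower and 827 genes higher and 3164 lower. Alu was at -0.39 and L1 at 0.15 in J2, and Alu at -0.36 and L1 at 0.049 in Input. With the upper quartile 1094 genes were lower in Input MPS1i against DMSO. J2 against Input in DMSO gave 3019 regions higher and 3827 genes higher and 686 lower, and in MPS1i 2543 regions higher and 683 lower and 3919 genes higher and 578 lower. Alu was at -0.31 and L1 at 0.23 in J2, and Alu at 0.22 and L1 at 0.63 in Input.

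Without the abundant RNAs, J2 against Input in DMSO gave 1059 regions higher and 953 genes higher and 1629 lower, and in MPS1i 973 regions higher and 1144 genes higher and 1479 lower. Alu was at -0.043 and L1 at 0.37 in Input MPS1i against DMSO. Without the 100 most-read regions, J2 against Input in DMSO gave 1007 regions higher and 894 genes higher and 1684 lower, and in MPS1i 890 regions higher and 1016 genes higher and 1589 lower. L1 was at 0.20 in J2, and Alu at -0.15 and L1 at 0.40 in Input.

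At a count minimum of 200, J2 MPS1i against DMSO gave 820 regions higher and 1257 lower and 523 genes higher, and Input 334 regions higher and 229 lower and 272 genes higher and 919 lower. J2 against Input in DMSO gave 753 regions higher and 305 lower and 384 genes lower, and in MPS1i 549 regions higher and 200 lower and 1066 genes higher and 361 lower. The change of J2 enrichment gave 137 regions higher and 77 lower and 329 genes higher and 373 lower. Without a count minimum J2 MPS1i against DMSO gave 54991 regions higher and 57472 lower and 4452 genes higher, and Input 99530 regions higher and 42561 lower and 3817 genes higher. J2 against Input in DMSO gave 3569 regions higher and 6324 lower and 2265 genes lower, and in MPS1i 4765 regions higher and 7722 lower and 3208 genes higher and 2456 lower. The change of J2 enrichment gave 3610 regions higher and 2962 lower and 1730 genes higher. The extra items had fewer than 50 counts.

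At a fold of 1.5, J2 MPS1i against DMSO gave 7407 regions higher and 3704 genes lower, and Input 4481 regions higher and 3658 lower and 1937 genes higher and 3163 lower. J2 against Input in DMSO gave 3819 genes higher and 1611 lower, and in MPS1i 2283 regions higher and 3552 genes higher and 1605 lower. The change of J2 enrichment gave 1727 genes higher and 1699 lower. With all libraries thinned to the shallowest, J2 MPS1i against DMSO gave 2823 regions higher and 4109 lower, and the change of J2 enrichment 581 and 384.

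Counting each region once gave 415 genes higher and 1032 lower in J2 MPS1i against DMSO, and 91 and 993 in Input. The minimum of 50 then applied to regions with a read, which fewer genes reach. A 2-fold ratio in both random sets of regions left 793 genes higher and 922 lower in Input. Sums per gene name of the tables gave 4636 genes higher in J2 MPS1i against DMSO and 3417 in Input. An overlap of 50% gave 8525 regions higher and 2825 lower in J2 against Input in DMSO, 4946 and 2250 in MPS1i, and 2316 and 2387 for the change of J2 enrichment. Sums per repeat subfamily in place of regions gave 135 higher and 85 lower in J2 MPS1i against DMSO, 145 and 42 in Input, 335 and 118 in J2 against Input in DMSO, 255 and 103 in MPS1i, and 76 and 92 for the change of J2 enrichment.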

Other observations

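Of the tests in this part, those of amplified fragments in Input, of leukocytes, of gene density and of RNA downstream of genes were chosen after the result was seen.

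RNA outside the annotated ends of interferon-stimulated genes was higher in MPS1i as well. In the 20 kb downstream on the same strand, 29 of 33 genes in Input and 31 of 33 in J2 were at least 2-fold higher, with medians of 3.94 and 4.04 against 0.50 and 0.67 for all genes. Of the leading genes, FBXO39, an F-box gene, starts 0.576 kb downstream of XAF1, and NRIR, a noncoding RNA, 0.106 kb downstream of CMPK2, both on the same strand. SLC16A12-AS1, an antisense transcript, starts 35.1 kb downstream of IFIT5, beyond that window, and FAP, a fibroblast protease looked up after its values were seen, 21.9 kb downstream of IFIH1. Transcription past the gene ends could explain FBXO39 and NRIR, which does not exclude promoters of their own. On the IFIT strand, J2 regions high in MPS1i followed one another, with gaps, from the end of IFIT5 towards SLC16A12-AS1. The last before its start at 89456064 ended at 89455223 and had 0 counts in DMSO and 95 in MPS1i. Transcription past IFIT5 could thus explain SLC16A12-AS1 as well, which was not tested.

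Reads antisense to interferon-stimulated genes were higher too. Reads on the opposite strand overlapping the genes were measured at 20 counts or more and called higher at 2-fold with an interval excluding 1. By that rule 21 of 24 genes were higher in Input (median 2.30) and 17 of 22 in J2 (median 2.55), where 1 was lower. The medians of all genes were 0.29 and 0.60. J2 did not favour these antisense reads, which came to 8.85% of the reads of the genes in MPS1i J2 and 10.2% in MPS1i Input, and to 10.4% and 12.7% in DMSO. Some of the regions span much of a gene, such as that of 32543 bp opposite to MX2, with 146 of its 148 antisense reads in MPS1i Input. Antisense transcripts were not told apart from reads of the gene placed on the wrong strand.

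Interferon-stimulated genes were higher in both tables, and technical causes were tested. A few over-amplified fragments were argued against by the number of regions with a read, whose median log2 ratio was 1.43 in J2 (all genes -0.40). In Input it was 0.69, which missed the bound of 1 first set, and it lay 1.97 above the -1.28 of all genes, a baseline added afterwards. Adjusting for gene length and for the GC content of the genes' transcripts left a median of 3.19. The GC content of the counted regions was not available, so it was not tested. Leukocytes among the cells stay open, since their marker genes were near the floor, with 12 reads in MPS1i Input and 5 in DMSO Input (2.48 and 0.783 CPM), and 2.84 and 0.715 CPM in J2. Also open is whether another culture would give the same. Whether the response arose from RNA or DNA sensing was not tested. Genes of both kinds went both ways, DDX58 and IFI16 higher and MAVS and CGAS lower, and their levels do not tell which sensor acted.

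Chromosomes differed in J2. Their median log2 ratios had an SD of 0.345, from -0.94 on chromosome 22 to 0.38 on chromosome 4, and an SD of 0.194 in Input, from -0.61 on chromosome 22 to 0.14 on X. Adjusting for the GC content of the genes' transcripts removed 15.0% of the SD in J2. The GC content of the counted regions, mostly outside exons, was not available, so GC content stays open. Adjusting for gene length removed 0.988%, which argues against it as the main cause. Gene density removed 27.8% and stays open, with medians of 0.24 among the sparsest and -0.55 among the densest genes. Loss or gain of chromosomes after errors in their separation could add to this, but was not tested.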
